A study of Mus musculus with 20 samples.

How the data were processed

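Islet RNA from 20 male ob/ob mice was measured on 1-colour Agilent arrays, 1 array per mouse and 5 mice per group. The groups were 18 weeks of the diet labelled HFD (young_HFD), 18 weeks of HFD and then 2 days of the diet labelled CRD (young_CRD), and the same pair at 39 weeks (aged_HFD and aged_CRD). The labels do not spell out the 2 abbreviations. Per the labels' protocols, islets were freed with collagenase, picked by hand away from exocrine tissue and frozen, and RNA passed an integrity limit before labelling with Cy3. The labelling protocol names oligo-dT primer or a mixture with random primers, and which array had which is not given in the sources used here.

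The deposited table held 1 intensity per probe and array for 59448 probes, on a linear scale. Image analysis used Agilent Feature Extraction 11, per the submitters' processing notes. Background correction, detection flags and the software that normalized the values are not given in the sources used here. All 20 columns held identical sorted values, so the authors' intensities were quantile normalized before deposit, and the median (36.39), the 75th percentile (195.1), the lowest (1.466) and the highest value were the same on every array. Scale and direction are therefore those of an intensity, while the background level stayed unknown. The number of arrays limits the precision of every value.

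The intensities were used as log2. A probe was named through the platform table given for this work, in which 30010 probes had 1 gene symbol, 0 had several and 29438 had none. All 30010 gene identifiers matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was used for names only. For the 3324 genes with over 1 probe, the probe with the highest mean over all arrays stood for the gene. The lowest 30% of the 26159 genes by mean level over all arrays were left out, at a mean log2 intensity of 4.83, which left 18311 genes. Each fold change is on the log2 scale with its standard error (SE), and group levels are means with the standard deviation (SD). Ins1 is not analysed here.

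Fold changes came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 20 arrays in 4 groups, with Benjamini-Hochberg adjustment over the 18311 genes and a threshold of 0.05. The contrasts were CRD against HFD at 18 weeks, CRD against HFD at 39 weeks, 39 against 18 weeks on HFD, 39 against 18 weeks after CRD, and the difference between the 2 CRD effects. The 31 gene lists, 19 of pathways and 12 of cell type markers, held 596 entries, of which 476 were tested. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with camera at an estimated correlation and with fry. Members are counted over all genes tested and adjusted over the list alone. The contrasts, the lists, the rule for named genes and the alternatives of processing, except those named at the end, were chosen before the data were examined.

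Named genes followed a rule. In each contrast they were the 12 rising and the 12 falling genes with the largest fold change among those past the threshold whose 2 groups did not overlap, leaving out predicted and clone names. In each list they were up to 4 members past the threshold with the largest change, or up to 2 with the smallest p as values. Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Txnip, Mki67 and Aldh1a3 were always included. The clock genes Arntl, Npas2, Clock, Nfil3, Cry1, Per1, Per2, Per3, Ciart, Bhlhe40 and Bhlhe41, the cell cycle gene Mcm3 and the acinar gene Bhlha15 were named after their values were seen.

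The arrays fell into 3 array sets that no label records. They were found after the data were seen, by average-linkage clustering of the arrays on 1317 chemosensory receptor genes (olfactory, vomeronasal, trace amine and taste receptor families). As each set except the smallest held more than 2 groups, the number of genes called in each contrast is given also with the array set as a block. For lists and named genes, blocked values and values within sets are given for a part of them. In the block fit the 18-week and the 39-week contrast share the array set terms, so the 12 arrays of set A were also fitted alone, where those 2 contrasts share no array. Its 18-week CRD arm is 1 array, which is assumed to vary like the other groups. Set B alone, fitted for CRD at 18 weeks only, has an HFD arm of 1 array, under the same assumption.

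The fit was tested on simulated data with the real spread of the 18311 genes and 200 genes changed by 1 or 2 on the log2 scale. For CRD at 18 weeks without array set effects it found 78% of the changes of 1 and all of the changes of 2, and called 12 unchanged genes. With the array set effects of the real data added, it found 49% and 89% and called 51 unchanged genes, and with the array set as a block 68% and 97% with 7 unchanged genes. For CRD at 39 weeks the same steps gave 40% and 94% without the block and 77% and 99% with it. The simulated noise was independent between genes, while genes of the real arrays also varied together within an array set. These shares and counts may therefore not carry over to the real data. The alternatives covered normalization, the filter on dim genes, the treatment of probes, the limma settings, array weights, the number of groups in the fit, blocks on the label numbers, marker means as covariates and leaving out each array in turn. The array set, set A or B alone, the block with the acinar mean, and an offset of 16 added before the log were chosen after seeing the data.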

Results

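Pancreatic islets of male ob/ob mice, which lack functional leptin and become obese, were profiled on 20 arrays in 4 groups of 5 mice. The series sets 18 weeks of HFD (young) against 39 weeks of HFD (aged), and at each age sets mice kept on HFD against mice moved to CRD for 2 days. The labels give age and weeks of HFD as the same number, so the 2 could not be told apart, and age stands for both here. Ins2, which encodes insulin, reached the highest value of the table on most arrays, with group means of 17.89 to 17.94, so no change in it could be read. Gcg (glucagon) had a mean log2 intensity of 14.81 ± 0.45 (SD, n = 5) in young_HFD, Sst (somatostatin) 14.56 ± 0.39 and Ppy (pancreatic polypeptide) 13.98 ± 0.35.

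On 1317 chemosensory receptor genes the arrays split into 3 array sets that cut across the groups. Correlations were 0.925 to 0.979 within a set and 0.848 to 0.917 between sets. Set A held 4 young_HFD, 1 young_CRD, 3 aged_HFD and 4 aged_CRD arrays, set B held 1, 4, 1 and 0, and set C held 1 aged_HFD and 1 aged_CRD array. At 18 weeks the sets therefore lay almost along the diet. The first principal component of the genes tested held 52.95% of the variance and the second 16.02%. On the first, set B lay at -61.82 to -89.9, set C at -9.067 and -11.1 and set A at -0.8866 to 108.9. The young_HFD arrays of set A alone spanned that last range, a spread within a set that the array set as a block does not remove. On the second, every HFD array lay above 0 and every CRD array below it. Of all pairs of arrays the highest correlation was 0.99 and 0 pairs were identical.

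After 2 days of CRD at 18 weeks, most of the tested cell cycle genes rose. Genes of protein folding in the endoplasmic reticulum rose as well (21 of 26, and 11 with the array set as a block). The glucose transporter gene Slc2a2 and 5 genes of the circadian clock or its output fell. Mki67, a marker of cycling cells, went from 6.17 ± 0.47 to 10.04 ± 0.85 (SD, n = 5), a log2 fold change of 3.87 ± 0.38 (SE). Slc2a2, which encodes the main glucose transporter of mouse beta cells, went from 12.30 ± 1.08 to 9.49 ± 0.79, a change of -2.81 ± 0.48. In total 3120 of 18311 genes rose and 1445 fell, and 1757 genes (9.595%) had no overlap between the 2 groups, where chance gives 0.7937%. That chance share leaves out the array sets, which lay almost along the diet here, so the excess is not one of diet alone. Age after CRD, with 0 genes called in the block fit, had 836 genes (4.566%) without overlap.

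Of 30 tested cell cycle genes, 25 rose and 1 fell at 18 weeks (26 and 1 adjusted over the list alone), with a median log2 fold change of 3.08. The camera call (adjusted p = 2.07e-23) was lost there, at adjusted p = 0.147 with an estimated correlation, and passed with the array set as a block (adjusted p = 0.0277 with an estimated correlation), where 25 rose and 0 fell. Without an offset the largest rise was in Birc5, which encodes the mitotic protein survivin (6.30 ± 0.55). Next to it were the spindle factor Tpx2 (5.77 ± 0.56), the mitotic kinase Plk1 (5.44 ± 0.37), topoisomerase Top2a (5.09 ± 0.47), the centromeric histone Cenpa (4.98 ± 0.36) and the anaphase activator Cdc20 (4.82 ± 0.39). Others were the cyclin Ccna2 (4.64 ± 0.39), Cdca3 (4.62 ± 0.35), the cyclin-dependent kinase Cdk1 (4.53 ± 0.36) and Uhrf1 (4.41 ± 0.49), which maintains DNA methylation. Serpina7, which encodes a carrier of thyroid hormone, rose by 5.36 ± 0.31 and D17H6S56E-5 by 4.80 ± 0.46. The replication gene Mcm3 fell (-1.53 ± 0.43), and with the array set as a block it did not pass (-0.52, adjusted p = 0.253). Within set A it was higher (0.28), which rests on 1 CRD array, young_CRD replicate 2. Within set B it was lower on every CRD array (12.52 to 13.06) than on the young_HFD array (13.91). Several of these genes were dim on HFD: Birc5 had a mean of 1.99 ± 1.31 there, so the fold changes and their order depended on the unknown background. With an offset of 16 before the log the fold change of Birc5 was 3.98 ± 0.31, below Serpina7 (5.19 ± 0.30) and Top2a (4.56 ± 0.41).

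The 12 largest falls at 18 weeks held 5 genes of the circadian clock or its output, Hlf (-2.66 ± 0.27), Dbp (-2.57 ± 0.22), Tef (-2.55 ± 0.31), Nr1d2 (-2.26 ± 0.31) and Nr1d1 (-1.97 ± 0.17). No fixed list covered the clock, and Per1 (-0.07 ± 0.29), Per2 (-0.16 ± 0.30), Per3 (-0.22 ± 0.28), Ciart (0.21 ± 0.24), Bhlhe40 (0.27 ± 0.34) and Bhlhe41 (-0.43 ± 0.28) did not pass. The 12 also held Slc2a2 and Cox6a2 (-2.89 ± 0.36), a subunit of cytochrome oxidase. The others were the sulfotransferase Sult1d1 (-2.20 ± 0.29), the calmodulin-binding Pcp4 (-2.02 ± 0.30), the transporter Slc16a9 (8.45 ± 0.56 to 6.45 ± 0.31, SD), mesothelin Msln (-1.97 ± 0.33) and the early-response nuclear receptor Nr4a1 (-1.97 ± 0.37). Of 22 tested genes of beta-cell identity and glucose sensing, 12 fell and 0 rose (12 and 0 adjusted over the list alone), with camera adjusted p = 5.74e-05 and adjusted p = 0.419 with an estimated correlation. Beside Slc2a2 they included Glp1r, the receptor of the incretin hormone GLP-1 (-1.82 ± 0.15), the zinc transporter of insulin granules Slc30a8 (-1.81 ± 0.25) and the transcription factor Neurod1 (-1.09 ± 0.22). In the block fit 11 of the 22 fell, at adjusted p = 0.0277 with an estimated correlation. Pdx1 (-0.97 ± 0.26) and Mafa (-0.56 ± 0.19), transcription factors of beta cells, fell as well, and neither passed with that block (adjusted p = 0.0934 and 0.374).

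Of 26 tested endoplasmic reticulum chaperones and XBP1 or ATF6 targets, 21 rose and 1 fell at 18 weeks (22 and 1 adjusted over the list alone). The camera adjusted p of 1.13e-10 became adjusted p = 0.75 with an estimated correlation, and 11 rose with the array set as a block. Derl3, of the degradation of misfolded proteins, rose by 3.19 ± 0.26, Creld2 by 2.65 ± 0.26, Sdf2l1 by 2.41 ± 0.21 and the prolyl isomerase Fkbp11 by 2.26 ± 0.21. Of 30 oxidative phosphorylation genes 19 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 1.96e-08, adjusted p = 0.915 with an estimated correlation), and 9 rose with the block. Cycs, which encodes cytochrome c, rose by 2.27 ± 0.38, Ndufa4 by 1.58 ± 0.17 and Cox7b by 1.42 ± 0.22. Antioxidant genes numbered 10 up and 1 down of 19 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00186, adjusted p = 0.915 with an estimated correlation). The block fit had 5 up and 1 down, with no camera call (adjusted p = 0.0726). Gpx3 rose by 1.53 ± 0.22 and thioredoxin Txn1 by 1.46 ± 0.21. Txnip, the glucose-induced inhibitor of thioredoxin, rose by 2.27 ± 0.53, and Arrdc4, like it a target of the glucose sensor ChREBP, by 1.94 ± 0.25. Within the array sets the difference of Txnip was smaller. It was 1.13 in set A, and in set B the levels were 13.78 on the young_HFD array and 15.06 to 15.49 after CRD. Mlxipl, which encodes ChREBP, fell by 1.22 ± 0.28 on the log2 scale. In that list of ChREBP and lipogenic genes 6 of 22 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.483).

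Among genes of dedifferentiation or normally shut off in beta cells, 5 of 12 rose at 18 weeks (8 adjusted over the list alone; camera adjusted p = 0.0165, adjusted p = 0.915 with an estimated correlation), and 2 of 12 with the array set as a block. They included ornithine aminotransferase Oat (1.97 ± 0.35) and Aldh1a3 (1.79 ± 0.25), an aldehyde dehydrogenase used as a marker of dedifferentiated beta cells. Secretory granule genes went both ways, 3 up and 5 down of 21 (5 and 6 adjusted over the list alone; camera adjusted p = 0.864). Scg3 (1.44 ± 0.30) and the granule membrane protein Ptprn (1.24 ± 0.16) were higher and the fusion protein Snap25 (-1.17 ± 0.25) was lower. Glycolysis genes had 4 up and 1 down of 15 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0357, adjusted p = 0.915 with an estimated correlation), with Gapdh at 1.16 ± 0.19. In the block fit 2 rose, the median was 0.04 (0.36 without it) and the camera call was lost (adjusted p = 0.409). Heat shock genes had 5 up of 13 (7 adjusted over the list alone; camera adjusted p = 0.0165, adjusted p = 0.915 with an estimated correlation). With the block 0 passed, the median was 0.33 (0.94 without it) and the camera call was lost (adjusted p = 0.395). The median was 0.63 within set A and -0.19 within set B.

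The remaining pathway lists had no camera call at 18 weeks. Adjusted over the list alone, cholesterol synthesis had 9 up and 2 down of 18 (8 and 1 over all genes), fatty acid oxidation 4 up and 2 down of 19 (the same over all genes), with the dehydrogenase gene Hadh at -1.10 ± 0.37. The integrated stress response had 1 up and 1 down of 21. Senescence had 3 up and 1 down of 11, interferon response 2 up of 12 and inflammatory cytokine response 1 down of 11, which was Nfkbia (-0.97 ± 0.23). On the same basis extracellular matrix had 2 up and 1 down of 20, the last being perlecan Hspg2 (-0.83 ± 0.21). With the block Hspg2 was at -0.49 ± 0.19 (adjusted p = 0.0937), and it differed by -0.71 within set A and -0.17 within set B. Also over the list alone, primary cilium had 5 up and 4 down of 31, and immediate early genes 1 down of 18, which was Nr4a1. Over all genes these counts were the same except for 0 senescence genes and 3 cilium genes down. The blocked counts over all genes were 4 up and 2 down for cholesterol, 0 and 1 for fatty acid oxidation, 1 and 3 for the integrated stress response, 0 and 2 for senescence, 2 and 0 for interferon and 1 and 1 for inflammatory cytokines. For matrix they were 0 and 1, for cilium 2 and 3, for immediate early genes 0 and 2, for secretory granule 3 and 4 and for ChREBP 3 and 2. For the secretory granule and the inflammatory cytokine list, which had no call, the median was above 0 (0.20 and 0.23) and the direction given by camera was down.

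Of 20 tested acinar markers, 10 rose and 0 fell at 18 weeks (13 and 0 adjusted over the list alone; camera adjusted p = 0.00353, adjusted p = 0.915 with an estimated correlation), with the trypsinogen Try4 at 3.05 ± 0.99. Only 1 passed with the array set as a block, the transcription factor gene Bhlha15, and Try4 did not pass there (3.04 ± 1.19). The list median was 1.63 there, against 1.79 without it, and camera called it (adjusted p = 0.000688, adjusted p = 0.811 with an estimated correlation). The other 11 cell type lists had no camera call without the block. Camera with the block called the delta-cell markers as lower (median -0.56, adjusted p = 0.0073, adjusted p = 0.239 with an estimated correlation), with 2 of 6 down. Among alpha-cell markers 1 of 8 passed, Ttr (2.01 ± 0.21), which encodes transthyretin, and Gcg did not (-0.41 ± 0.27). The block gave 1 alpha-cell marker up and 3 down, with Gcg at -0.93 ± 0.20 (adjusted p = 0.00353). Delta-cell markers had 1 down of 6, with Sst at -0.48 ± 0.26, and PP-cell markers 1 down of 5 (2 adjusted over the list alone), which was Ppy (-0.65 ± 0.22). Ppy did not pass with the block (-0.39 ± 0.22, adjusted p = 0.309) and differed by -0.06 within set A. Within set B it was lower on every CRD array (12.85 to 13.42) than on the young_HFD array (13.67). Adjusted over the list alone, 2 duct markers of 6, 0 macrophage markers of 12, 0 T- and B-cell markers of 12 and 0 endothelial markers of 13 passed. Stellate and fibroblast markers had 3 up and 1 down of 11, adipocyte markers 0 of 6, erythroid markers 0 of 3 and Schwann-cell and neural markers 1 of 3. Over all genes the counts were the same except for 2 macrophage, 1 T- and B-cell and 1 endothelial marker up. The block gave 1 macrophage, 1 stellate and fibroblast and 1 adipocyte marker down, 1 Schwann-cell and neural marker up, and no duct, T- and B-cell, endothelial or erythroid marker past the threshold.

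With the array set as a block, 1262 genes rose and 1093 fell at 18 weeks, 1783 of these being among the 4565 called without it, and the share of higher calls went from 68.35% to 53.59%. Of 79 named genes called at 18 weeks, 17 were not called with it: Amy1, Amy2a2, Amy2b, Cel, Cela2a, Cela3b, Dmbt1, Sycn, Try4, Cd79b, Ddx21, Hspa1a, Hspg2, Mafa, Mcm3, Pdx1 and Ppy. Within set A (4 against 1 array) Mki67 differed by 3.14 and Slc2a2 by -3.52, and within set B (1 against 4) by 3.55 and -3.80. The median of the cell cycle list was 2.47 and 2.17. The count also rested on single arrays: it was 8400 without young_HFD replicate 2, 7296 without young_CRD replicate 2, and 2614 without young_HFD replicate 4. It was 2789 without young_HFD replicate 5, 2851 without young_CRD replicate 3 and 2861 without young_CRD replicate 5.

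**Figure D1:**
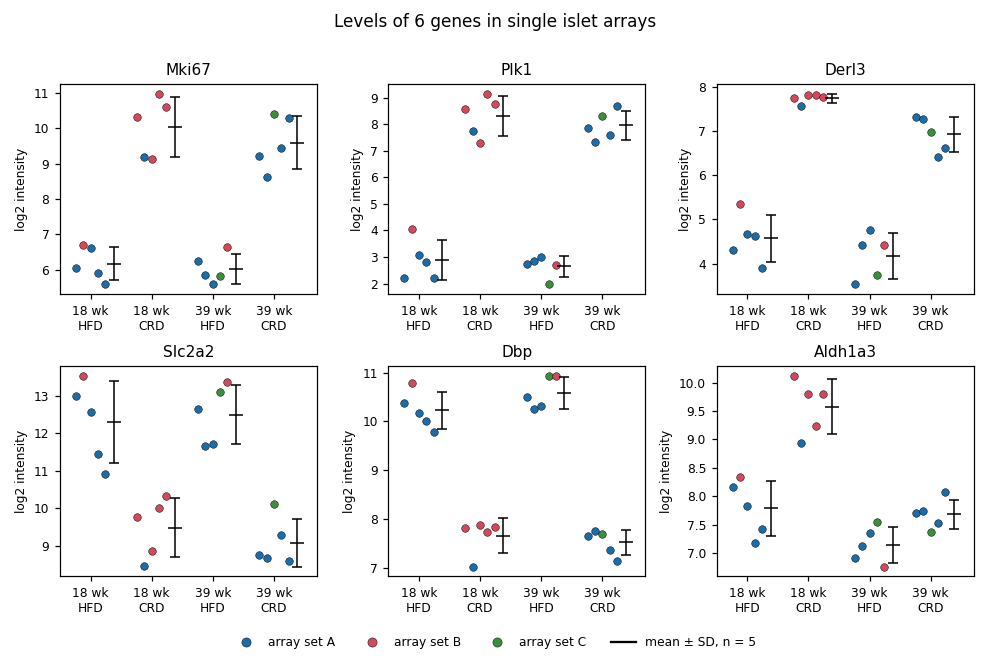
Log2 intensity (vertical axis) of 6 genes on each of the 20 arrays, by group (horizontal axis), with points coloured by array set and bars for the mean and SD of 5 mice. Mki67, Plk1 and Derl3 lay higher after CRD at both ages and Slc2a2 and Dbp lower, while Aldh1a3 rose by 1.79 at 18 weeks and had a difference of 0.55 at 39 weeks that did not pass the test.

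After 2 days of CRD at 39 weeks, most of the tested cell cycle genes and some endoplasmic reticulum chaperones rose. Slc2a2 and the same 5 genes of the clock or its output as at 18 weeks fell. Mki67 went from 6.03 ± 0.42 to 9.60 ± 0.75 (SD, n = 5), a log2 fold change of 3.57 ± 0.38, and Slc2a2 from 12.50 ± 0.78 to 9.08 ± 0.63, a change of -3.42 ± 0.48. In total 641 genes rose and 887 fell. Of the genes tested, 2326 (12.7%) had no overlap between the groups, against 0.7937% by chance.

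Of the 30 cell cycle genes 25 rose and 0 fell at 39 weeks (25 and 0 adjusted over the list alone; camera adjusted p = 6.12e-42), and the call held at adjusted p = 0.0139 with an estimated correlation. Birc5 rose by 6.04 ± 0.55, Tpx2 by 5.55 ± 0.56, Plk1 by 5.31 ± 0.37 and Cdk1 by 5.22 ± 0.36. Uhrf1 rose by 5.17 ± 0.49, Top2a by 4.79 ± 0.47, Cdc20 by 4.68 ± 0.39, Cenpa by 4.32 ± 0.36, Cdca3 by 4.21 ± 0.35, Ccna2 by 4.14 ± 0.39 and the chromatin remodeller Hells by 4.12 ± 0.30. Serpina7 rose by 4.63 ± 0.31. Several of them were dim on HFD, so these fold changes depended on the unknown background. With an offset of 16 they were 3.61 ± 0.31 for Birc5, 3.35 ± 0.30 for Tpx2, 3.57 ± 0.28 for Plk1, 4.31 ± 0.41 for Top2a and 4.46 ± 0.30 for Serpina7. Of the 26 endoplasmic reticulum genes 10 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.738 with an estimated correlation), with Fkbp11 at 2.82 ± 0.21, Derl3 at 2.75 ± 0.26, Sdf2l1 at 2.53 ± 0.21 and Creld2 at 1.77 ± 0.26. The other 16 did not pass, and 13 rose with the array set as a block. Transthyretin Ttr rose by 1.55 ± 0.21, Arrdc4 by 1.79 ± 0.25, Ptprn by 1.18 ± 0.16, Gpx3 by 1.18 ± 0.22, Txn1 by 1.13 ± 0.21, Ndufa4 by 1.08 ± 0.17 and Gapdh by 0.81 ± 0.19.

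The falling genes at 39 weeks again held Dbp (-3.07 ± 0.22), Hlf (-2.98 ± 0.27), Tef (-2.95 ± 0.31) and Nr1d2 (-2.53 ± 0.31), with Nr1d1 at -1.46 ± 0.17. Of the other clock genes, Per2 (-1.65 ± 0.30) and Bhlhe41 (-1.05 ± 0.28) fell, and Per1 (-0.83 ± 0.29), Per3 (0.04 ± 0.28), Ciart (-0.01 ± 0.24) and Bhlhe40 (0.08 ± 0.34) did not pass. The others of the 12 largest included Slc2a2, the matrix protein gene Ltbp2 (-3.21 ± 0.44), the immediate early gene Egr1 (-2.58 ± 0.38) and the calcineurin-like Chp2 (-2.51 ± 0.31). The rest were Pcp4 (-2.50 ± 0.30), the peptidase Dpp7 (-2.40 ± 0.38), the glutathione transferase Gstm3 (-2.35 ± 0.27) and the sulfotransferase Sult1c2 (-2.25 ± 0.42). Of the 22 beta-cell genes 8 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 4.46e-06, adjusted p = 0.237 with an estimated correlation), including Slc30a8 (-1.93 ± 0.25), Glp1r (-1.58 ± 0.15) and Ero1b (-1.30 ± 0.34), an oxidoreductase of proinsulin folding. Mafa (-0.13 ± 0.19) and Pdx1 (-0.15 ± 0.26) did not pass. Integrated stress response genes fell in 5 of 21 cases (5 adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.764 with an estimated correlation), among them Trib3 (-1.59 ± 0.34) and the transcription factor gene Ddit3 (-0.83 ± 0.17). Primary cilium genes fell in 4 of 31 (5 adjusted over the list alone; camera adjusted p = 0.00166, adjusted p = 0.764 with an estimated correlation), with the transport gene Ift88 at -1.38 ± 0.34.

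Oxidative phosphorylation had 1 gene up of 30 at 39 weeks (1 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.897 with an estimated correlation), and 7 with the array set as a block. The acinar markers had 1 up and 5 down of 20 (1 and 15 adjusted over the list alone; camera adjusted p = 4.46e-06, adjusted p = 0.738 with an estimated correlation). The lipase Cel fell by 2.63 ± 0.81 on the log2 scale, a call lost on leaving out any 1 of 13 of the 20 arrays. The gene that rose was Bhlha15 (0.73 ± 0.20), a transcription factor of secretory cells. No other list had a camera call. Adjusted over the list alone, 0 of 12 dedifferentiation genes, 2 up and 3 down of 21 secretory granule genes and 2 up and 3 down of 22 ChREBP and lipogenic genes passed. So did 1 up and 1 down of 15 glycolysis genes, 1 down of 19 fatty acid oxidation genes, 1 up and 3 down of 18 cholesterol genes and 2 up of 19 antioxidant genes. Among them were the granule docking gene Sytl4 (-1.27 ± 0.27), Mlxipl (-1.75 ± 0.28) and Hadh (-1.56 ± 0.37). On the same basis 1 of 11 senescence and 1 of 12 interferon genes fell, 1 inflammatory cytokine gene rose and 2 fell of 11, with Nfkbia at -1.44 ± 0.23. Of 20 matrix genes 3 fell, with Hspg2 at -0.81 ± 0.21, 1 immediate early gene rose and 3 fell of 18, and 0 of 13 heat shock genes passed. Over all genes the counts were the same except for 2 secretory granule and 1 cholesterol gene down, no cholesterol gene up, and 2 inflammatory and 2 immediate early genes down with none up.

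Of the cell type markers at 39 weeks, adjusted over the list alone, 1 alpha-cell marker rose and 2 fell of 8, with Gcg at -0.90 ± 0.27, and 2 of 6 delta-cell markers fell, with Rgs2 at -1.95 ± 0.41. PP-cell markers had 0 of 5, duct markers 1 up and 1 down of 6, macrophage markers 1 down of 12, T- and B-cell markers 0 of 12 and endothelial markers 1 down of 13. Stellate and fibroblast markers had 3 down of 11, with decorin Dcn at -1.77 ± 0.41, adipocyte markers 3 down of 6, with lipoprotein lipase Lpl at -1.64 ± 0.34, erythroid markers 0 of 3 and Schwann-cell and neural markers 0 of 3. Over all genes 1 alpha-cell and 2 stellate and fibroblast markers fell, and the other counts were the same. Aldh1a3 (0.55 ± 0.25, adjusted p = 0.212) and Txnip (0.78 ± 0.53, adjusted p = 0.453) did not pass at 39 weeks, and Txnip passed with the array set as a block (1.13 ± 0.34, adjusted p = 0.0278).

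With that block 1372 genes rose and 1427 fell at 39 weeks, and these held all of the 1528 genes called without it. Within set A (3 against 4 arrays) Mki67 differed by 3.51 and Slc2a2 by -3.18, and in set C (1 against 1) by 4.58 and -3.00. The median of the cell cycle list was 2.54 and 3.11. The count of 1528 was 1004 without aged_HFD replicate 1.

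The 2 ages were set side by side to ask whether the response to CRD differed with age. Cell cycle genes had medians of 3.08 and 2.64 and beta-cell genes of -0.58 and -0.42 at 18 and 39 weeks. Of the genes called at each age, 585 rose at both, where independent lists would share 109.2, and 386 fell at both, where they would share 70. Of 972 genes called at both ages 1 moved in opposite directions, the acinar lipase gene Cel (2.38 ± 0.81 and -2.63 ± 0.81). The call of Cel was lost on leaving out any 1 of 5 of the 20 arrays at 18 weeks and of 13 at 39 weeks. With the array set as a block it was not called at 18 weeks. Across all 18311 genes, which are not independent replicates, the fold changes at the 2 ages had Pearson's r = 0.304 and Spearman's rho = 0.121. In the block fit r was 0.781 and rho 0.707. In set A alone, where the 2 contrasts share no array, r was 0.674 and rho 0.608, and the 18-week CRD arm was 1 array, young_CRD replicate 2. With no block r was 0.154 without aged_HFD replicate 2, 0.193 without young_HFD replicate 2 or without young_CRD replicate 2, and 0.518 without aged_HFD replicate 5.

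**Figure D2:**
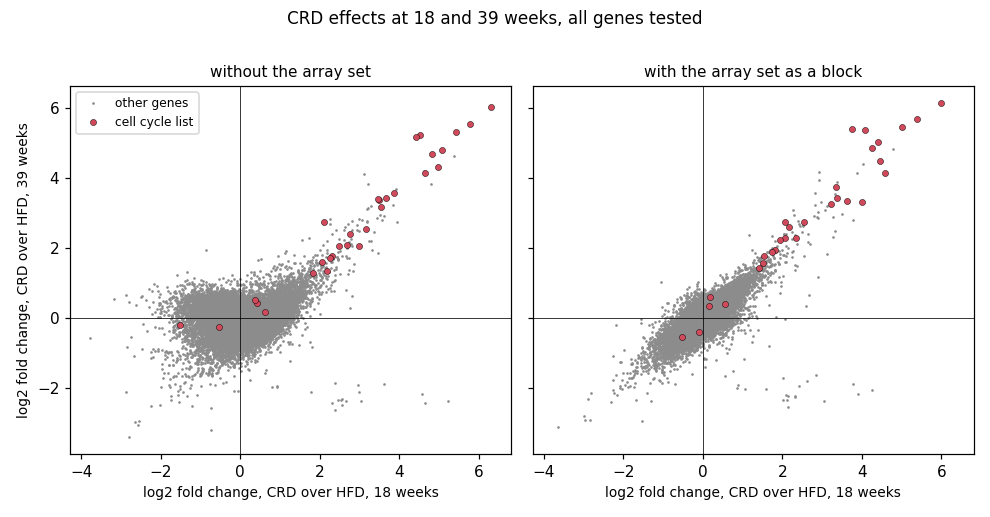
Log2 fold change of CRD over HFD at 18 weeks (horizontal axis) and at 39 weeks (vertical axis) for 18311 genes (grey points) and the 30 cell cycle genes (red points), without the array set and with it as a block. The cell cycle genes lay along the diagonal in both plots, and over all genes r was 0.304 in the left plot and 0.781 in the right one.

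In the test of the difference itself, limma called 0 genes (4043 at an unadjusted p under 0.05, lowest adjusted p = 0.222), and 0 with the array set as a block (327 at an unadjusted p under 0.05). The difference was -0.81 in median for the dedifferentiation list (camera adjusted p = 0.0243), and -0.27 with the block (adjusted p = 0.0133). For the acinar list, whose median was above 0 at 18 and below 0 at 39 weeks, it was -3.40 (adjusted p = 8.36e-10) and -3.36 with the block (adjusted p = 1.52e-32). The oxidative phosphorylation (median -0.71), endoplasmic reticulum (-0.74), integrated stress response (-0.66), antioxidant (-0.65), glycolysis (-0.61), heat shock (-0.77) and primary cilium (-0.74) lists were called without the block and not with it. With the block alone, camera called the beta-cell (median 0.21), cell cycle (0.17) and extracellular matrix (-0.31) lists. With an estimated correlation no list was called (adjusted p = 0.81 with an estimated correlation for these 9 lists). The interaction count was 3876 without young_HFD replicate 2 and 18 without young_HFD replicate 1.

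On HFD, the islets of aged mice had a higher mean level of acinar digestive enzyme transcripts than those of young mice. The array young_HFD replicate 1 lay near the aged arrays. Of 100 splits of the arrays 5 called at least 17 genes, the real count, so chance could not be excluded. Amy2b, Amy1 and Amy2a2, which encode amylases, were higher by 6.98 ± 1.28, 6.48 ± 1.13 and 6.39 ± 1.15, Try4 by 5.71 ± 0.99 and Dmbt1 by 5.29 ± 0.94. So were the lipase Cel by 5.09 ± 0.81, the granule protein Sycn by 4.80 ± 0.84 and the elastases Cela2a and Cela3b by 4.76 ± 0.83 and 4.74 ± 0.79. Amy2b was at 10.02 on young_HFD replicate 1 and 5.39 on replicate 2, against 10.11 to 11.39 on the aged_HFD arrays. On young_HFD replicates 3 to 5 it was at 0.88, 0.63 and 1.49, near the bottom of the scale. The amylase fold changes therefore depended on the unknown background. With an offset of 16 they were 4.99 ± 0.93, 5.44 ± 0.94 and 5.05 ± 0.92. Of 20 acinar markers 9 rose (17 adjusted over the list alone), with a median of 3.36 and camera adjusted p = 1.85e-33 (adjusted p = 0.0689 with an estimated correlation). The RNA helicase gene Ddx21 (-1.47 ± 0.27) and the microtubule linker Hook1 (-1.10 ± 0.21) fell. In total 13 genes rose and 4 fell, with 1209 at an unadjusted p under 0.05.

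Other calls of camera with age on HFD were lost with an estimated correlation. Beta-cell genes had 0 of 22 past the threshold (5 down adjusted over the list alone; camera adjusted p = 0.00043, adjusted p = 0.421 with an estimated correlation), with Glp1r at -0.63 ± 0.15 and Pdx1 at -0.94 ± 0.26. Erythroid markers had 0 of 3 (2 up adjusted over the list alone; camera adjusted p = 0.00043, adjusted p = 0.0689 with an estimated correlation), with the haemoglobin gene Hbb-bs at 1.07 ± 0.30. Oxidative phosphorylation (median 0.23), interferon response (0.31) and stellate and fibroblast markers (-0.27) had camera adjusted p = 0.0118, 0.0118 and 0.00624, each at adjusted p = 0.966 with an estimated correlation, and the block fit lost the call of the first (adjusted p = 0.149). In the other 25 lists no call was made. Cell cycle genes had 0 of 30, with Mki67 at -0.15 ± 0.38.

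In the block fit 30 genes rose and 137 fell with age on HFD, the 17 among them. This comparison and that of CRD at 18 weeks share the 5 young_HFD arrays, and across genes their fold changes had r = 0.406 and a covariance of 0.103, where shared arrays alone gave 0.505 and 0.052 in simulated data. The count went to 283 without young_HFD replicate 1, 47 without young_HFD replicate 2, 114 without young_CRD replicate 2 and 100 without aged_HFD replicate 5. It went to 0 without any 1 of young_HFD replicates 3, 4 and 5, aged_HFD replicates 1 to 4 and aged_CRD replicate 4. It was 8 to 11 without young_CRD replicate 1, 4 or 5 or aged_CRD replicate 1 or 2.

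**Figure D3:**
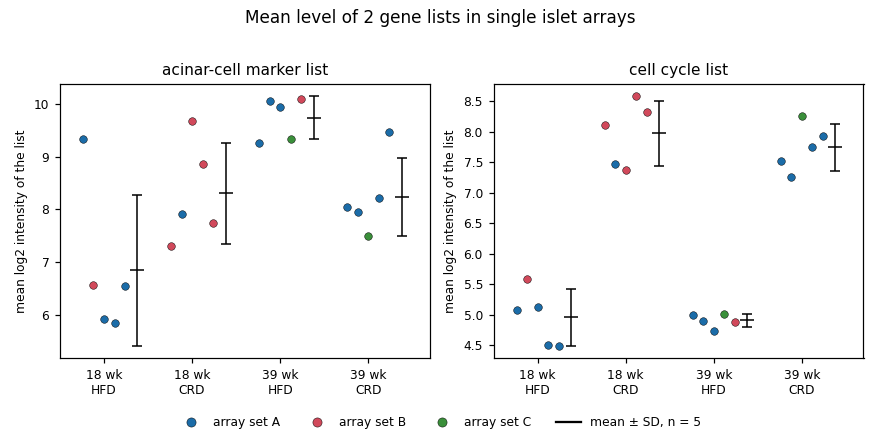
Mean log2 intensity (vertical axis) of the acinar markers and of the cell cycle list on each array, by group (horizontal axis), with points coloured by array set and bars for the mean and SD of 5 mice. The means hold all members measured on the array, also the dim ones left out of the tests. The acinar mean was 9.32 on young_HFD replicate 1 and had a median of 6.55 in that group, and the cell cycle list stood higher after CRD on every array than on any HFD array.

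After CRD, 5 genes were lower at 39 than at 18 weeks and 0 were higher (6510 at an unadjusted p under 0.05). They were the phosphatase Inpp4b (-1.92 ± 0.27), Aldh1a3 (-1.90 ± 0.25), Dbt of branched-chain amino acid breakdown (-1.40 ± 0.25), the laminin Lama5 (-1.35 ± 0.20) and the membrane trafficking gene Ehd2 (-1.23 ± 0.20). Stellate and fibroblast markers had 0 of 11 past the threshold and 9 down adjusted over the list alone (median -0.85, camera adjusted p = 0.000467, adjusted p = 0.838 with an estimated correlation), with Dcn at -2.14 ± 0.41 (adjusted p = 0.0892). Extracellular matrix genes had 1 up and 11 down of 20 adjusted over the list alone and 0 of 20 over all genes (median -0.63, camera adjusted p = 0.0155, adjusted p = 0.838 with an estimated correlation). Other lists with a camera call were the endoplasmic reticulum (median -0.60), heat shock (-0.73), oxidative phosphorylation (-0.48), integrated stress response (-0.52), primary cilium (-0.42), antioxidant (-0.43) and dedifferentiation (-0.52) lists, all at adjusted p = 0.838 with an estimated correlation, while the median of all genes was -0.18. Of these 7 lists only the endoplasmic reticulum list kept its camera call with the block. The medians of oxidative phosphorylation (0.09), primary cilium (0.07), antioxidant (0.07) and dedifferentiation (0.01) were then above 0, and heat shock was at -0.14 and the integrated stress response at -0.02. The acinar list had a median of -0.04 without the block, 0.14 with it and 0.56 in set A alone.

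Limma with the array set as a block called 0 genes with age after CRD (305 at an unadjusted p under 0.05), and Aldh1a3 had a difference of -1.64 ± 0.31 (adjusted p = 0.325). The stellate and fibroblast (median -0.52) and extracellular matrix (-0.22) lists were called by camera with the block too, both at adjusted p = 0.0824 with an estimated correlation, as was the endoplasmic reticulum list (-0.17, adjusted p = 0.895 with an estimated correlation). Camera with the block also called the fatty acid oxidation (median 0.23), interferon (0.37) and erythroid (0.70) lists as higher, at adjusted p = 0.767, 0.523 and 0.174 with an estimated correlation. Young_CRD held 4 arrays of set B and aged_CRD none, so the 2 groups met only in set A, with 1 against 4 arrays (Aldh1a3 differed by -1.17 and Dcn by -1.15 there). The count of 5 was 6466 without young_CRD replicate 2, 58 without young_HFD replicate 2, and 3 without any 1 of young_CRD replicates 1, 3, 4 and 5 and aged_CRD replicates 4 and 5.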

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

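The counts of splits and the camera and fry tests of the interaction without the block were planned before the data were examined. Every other test in this part was chosen after the result it bears on was seen.

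Without the array sets in the fit, more genes were called for CRD at 18 than at 39 weeks (4565 against 1528). With the array set as a block the ratio of the counts was 0.841. A split of the 10 arrays of 18 weeks along the array sets called 11357 genes, more than the diet. That split kept 4 young_HFD arrays on 1 side and 4 young_CRD arrays on the other, so its count mixes set and diet. The sets were also found from these same arrays, so a high count was likely in advance and is no support for a cause. A much weaker response at 39 weeks is argued against by the noise-corrected spread of the blocked fold changes, whose ratio of 39 over 18 weeks was 0.986 (0.881 to 1.124 without any 1 array). In set A alone it was 0.857. Without the block it was 0.614, on the side of a weaker response, but there the array sets lie almost along the diet at 18 weeks and add to the spread. A slightly weaker response stays open. A technical difference between the array sets, found from the data and named in no label, is therefore a candidate explanation for the higher count at 18 weeks. What sets them apart, such as labelling primer or day, stays open.

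Acinar transcripts were higher at 39 than at 18 weeks of HFD. The array sets as the whole cause are argued against by the blocked median of 3.517. A rise of that size with age whatever the diet is argued against by the median after CRD, which was -0.039. Its SD over the members (0.406) is a spread of genes that move together, not of mice. On single arrays the mean of the acinar list was 7.32 to 9.68 in young_CRD and 7.50 to 9.46 in aged_CRD. As young_CRD lay mostly in set B and aged_CRD not at all, the median after CRD was also taken with the block (0.139, SD 0.311) and in set A alone (0.56, SD 0.448, 1 against 4 arrays), below the 3.359 on HFD. A smaller rise after CRD stays open, as the median of 0.56 in set A alone rests on 1 young_CRD array. Exocrine tissue carried over with the islets may account for the higher level on HFD, although the protocol picks islets by hand to remove that tissue. Over 20 acinar genes the median correlation of a gene with the mean of the others within groups was 0.936 (0.172 to 0.991). Acinar genes that move together for any reason would give this too, so it does not tell the causes apart. The array young_HFD replicate 1 also lay far from its group (acinar mean 9.32, group median 6.55). An effect of age on HFD alone on the islets' own transcripts was not tested and stays open.

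The genes of the clock or its output Dbp, Tef, Hlf, Nr1d1 and Nr1d2 were lower after CRD at both ages. They were picked from the largest falls, and the pattern does not cover the clock as a whole: Per3, Ciart and Bhlhe40 did not pass at either age with or without the block. Per1 passed at both ages with the block only, and Per2 and Bhlhe41 fell at 39 weeks. The array sets as the cause are argued against by the blocked medians of -2.89 at 18 and -2.798 at 39 weeks. A shifted clock phase at collection would raise the antiphase genes (Arntl, Npas2, Clock, Nfil3 and Cry1) at both ages, and their blocked medians were 0.774 and 0.346 with members that went both ways, so it cannot be told apart from an effect of the diet on these genes. The hour of collection is not given in the sources used here.

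For CRD at 18 weeks 4 of 100 splits of the arrays gave at least 4565 genes, the real one included. That share is low for chance alone. As the array sets lay almost along the diet, it cannot tell diet from array set. The highest other split (11357) followed the array sets, and the blocked count was 2355. For CRD at 39 weeks 1 of 100 splits, the real one, gave at least 1528 genes, with 18 in the highest other split. As the real split is counted, 1 of 100 is the lowest share possible, so chance can be excluded at that share only. For age on HFD 5 of 100 gave at least 17 genes, the highest other 7753, so chance cannot be excluded, and the blocked count was 167. For age after CRD 3 of 100 gave at least 5 genes, and the blocked count was 0. The highest other gave 6009 with the 4 set B arrays of young_CRD on 1 side, a split that mixes array set and age. For the difference between the CRD effects the real count was 0, so 100 of 100 splits gave as many, and the highest other gave 5632.

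Camera on the interaction called the acinar markers, with a median difference between the CRD effects of -3.398, and the dedifferentiation list, with -0.812 (adjusted p = 8.36e-10 and 0.0243, both at adjusted p = 0.81 with an estimated correlation). With the array set as a block the medians were -3.36 and -0.27, and by fry without it the adjusted p was 0.113 and 0.129. Of 11117 tested probes without a gene name, which the comparisons of genes leave out, 918 changed the same way with CRD at both ages with the array set as a block.

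In 422 tests of a group of 5 arrays for 1 array far from the rest (its gap to the nearest divided by the group's range), 32 exceeded the limit of 0.71, where chance gives about 1 in 20, or 21.1. Of these 12 were in young_CRD replicate 2, the 1 array of its group in set A. They were Dbp (0.84), Slc16a9 (0.865), Sdf2l1 (0.783), Ndufa4 (0.741), Txnip (0.787), Mlxipl (0.869), Txn1 (0.779), Ttr (0.72), Clock (0.897), Mcm3 (0.81), Per3 (0.833) and Ciart (0.774). In aged_CRD replicate 5 they were Egr1 (0.733), Amy2b (0.738), Amy2a2 (0.741), Try4 (0.848) and Cela3b (0.724), and in young_HFD replicate 1 Try4 (0.714), Cel (0.757), Cela3b (0.732) and the acinar list (0.794). The others were Slc16a9 (0.766), Mlxipl (0.851), Nfkbia (0.747) and Ciart (0.753) in aged_CRD replicate 4, Cox6a2 (0.767) and Slc30a8 (0.84) in aged_CRD replicate 3, Npas2 (0.89) and Cd79b (0.718) in aged_HFD replicate 4, Cox6a2 (0.773) in young_CRD replicate 3 and Sst (0.773) in aged_HFD replicate 5. Ins2 in aged_HFD replicate 3 had a value of 1, because the other 4 arrays were at the top of the scale.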

How the results depend on the processing

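The array set, set A or B alone, the offset of 16 and the block with the acinar mean, and the correlations of pairs by title number, were chosen after seeing the data, and the other alternatives before. Quantile normalization and centring on the median or the 75th percentile moved nothing, since the values were quantile normalized already, so they say nothing about stability. The fold changes of dim genes depend on the unknown background level, and of 79 named genes called at 18 weeks 78 were called with the offset. In the block fit 62 of the 79 were called. Set A alone held 1 young_CRD array and set B alone 1 young_HFD array, so no count at 18 weeks is given for them. At 39 weeks 65 of 65 were called with the block and 49 in set A alone. Where no cause is given, the cause was not tested.

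Counts below are of genes called. With the array set as a block they were 2355 (CRD at 18 weeks), 2799 (CRD at 39 weeks), 167 (age on HFD) and 0 (age after CRD by limma, with 305 at an unadjusted p under 0.05), and r between the ages was 0.781. In set A alone, with fewer arrays and 1 array of young_CRD (assumed to vary like the other groups), they were 180, 647, 0 and 0, with r = 0.674, and set B alone gave 1972 for CRD at 18 weeks. The block with the acinar mean gave 1439 for CRD at 18 weeks, 0 for both age comparisons and r = 0.773. The acinar mean alone gave 1508 and 779 for CRD at 18 and 39 weeks, 0 for age on HFD and r = 0.463. As most named genes called with age on HFD were acinar transcripts, the counts of 0 there were largely set in advance. The T- and B-cell mean gave 7448 for CRD at 18 weeks, 30 for age on HFD and 87 for age after CRD.

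Array weights gave 12510, 4409, 1605 and 14175 in the same order, 8105 for the difference between the CRD effects and r = 0.442. A fit of the 2 groups compared gave 2306 for CRD at 18 weeks, 0 for age on HFD and 4824 for age after CRD. Without the filter on dim genes age on HFD gave 0 and age after CRD 160, with the lowest 50% left out age after CRD gave 3, and with every probe on its own age on HFD gave 161. Leaving out 1 array gave 2614 to 8400 for CRD at 18 weeks, 1004 to 1884 at 39 weeks, 0 to 283 for age on HFD, 3 to 6466 for age after CRD, 0 to 3876 for the difference and r of 0.154 to 0.518.

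The check did not settle whether the mice were paired by the numbers in the labels, as it could miss pairs whose arrays lie in different array sets. Of 20 pairs with the same replicate number 3 had a correlation over 0.1 (range -0.85 to 0.371), and for 2 the best match had the same number. Of the 6 pairs with the same number in the sample title within an age 4 did (range -0.631 to 0.593). For 2, both at 39 weeks (0.156 and 0.339), the best match had the same number. With the title number as a random block the counts were 4566 and 1530 for CRD at 18 and 39 weeks. With the replicate number as a block the counts were 1004 for CRD at 39 weeks, 0 for age on HFD and 2 for age after CRD.

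Of the list tests over the 5 contrasts, camera called 33 of pathways and 7 of cell types. Pathway calls numbered 21 with the array set as a block, 11 by fry and 1 with an estimated correlation. Cell type calls numbered 3 with the acinar mean, which removes differences of the acinar list by construction, and 0 with an estimated correlation. Leaving out 1 array gave 29 to 39 and 5 to 9.

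The sign turned, with a call in at least 1 of the fits compared, for these genes and list medians. With CRD at 18 weeks these were Cd79b (-0.412) and Mcm3 (0.278) in set A alone. In set B alone, with 1 young_HFD array, they were Hspa1a (-0.206), heat shock (-0.193), glycolysis (-0.049), primary cilium (-0.289) and the integrated stress response (-0.277). With the block and the acinar mean they were glycolysis (-0.11) and primary cilium (-0.207).

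For age on HFD the acinar mean turned oxidative phosphorylation (-0.034) and the acinar list itself (-0.054). With the block added, these were -0.183 and -0.058, and endoplasmic reticulum (-0.208), antioxidant (-0.209) and heat shock (-0.424) turned too. The acinar covariate is the mean of the acinar list, so the loss of that list's own difference was set in advance and tests nothing. Leaving out 1 array gave -0.091 to 0.283 for endoplasmic reticulum.

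For age after CRD, 6 lists turned in the block fit, in set A alone and with the block and the acinar mean. These were oxidative phosphorylation (0.088, 0.042 and 0.068), antioxidant (0.065, 0.16 and 0.046), primary cilium (0.066, 0.052 and 0.052), dedifferentiation (0.008, 0.032 and 0.007), fatty acid oxidation (0.229, 0.164 and 0.199) and interferon response (0.371, 0.415 and 0.354). In set A alone the alpha-cell (0.158), acinar (0.56) and macrophage (0.179) lists turned as well, and array weights turned Pcp4 (0.267).

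In the difference between the CRD effects, the block turned the beta-cell (0.206) and cell cycle (0.166) lists, and set A alone the beta-cell (0.27) and antioxidant (0.017) lists. The block with the acinar mean turned cell cycle (0.329), glycolysis (0.185), fatty acid oxidation (0.248), endoplasmic reticulum (0.087), the integrated stress response (0.085) and antioxidant (0.228). It also turned oxidative phosphorylation (0.264), primary cilium (0.134), heat shock (0.301) and delta-cell markers (0.487).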

Other observations

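The clock genes in this part were chosen after their values were seen. Arntl, which encodes the activator BMAL1, rose with CRD at 18 weeks (2.66 ± 0.45, adjusted p = 0.000304), as did the repressors Nfil3 (2.25 ± 0.39, adjusted p = 0.000358) and Cry1 (1.16 ± 0.25, adjusted p = 0.00247), while Clock fell (-0.73 ± 0.26, adjusted p = 0.0471). The call of Clock was lost on leaving out any 1 of 16 of the 20 arrays, and without young_CRD replicate 2 its difference was -0.42 (adjusted p = 0.0834). The blocked value was -1.14 ± 0.25 (adjusted p = 0.00439). At 39 weeks Arntl had a difference of 0.78 ± 0.45 (adjusted p = 0.35), Nfil3 of 0.85 ± 0.39 (adjusted p = 0.206) and Cry1 of -0.06 ± 0.25, and Per2 fell (-1.65 ± 0.30, adjusted p = 0.00116), with a difference of -0.16 ± 0.30 at 18 weeks. Npas2 had differences of 0.10 ± 0.26 and 0.34 ± 0.26. With the array set as a block Arntl had 1.96 ± 0.44 at 18 weeks (adjusted p = 0.00479) and 1.02 ± 0.38 at 39 weeks (adjusted p = 0.08), and Nfil3 passed at both ages (adjusted p = 0.00506 and 0.0441). Per2 had -0.73 ± 0.26 at 18 weeks (adjusted p = 0.0708) and -1.46 ± 0.22 at 39 weeks (adjusted p = 0.000125) in that fit.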
